A study of Arabidopsis thaliana with 18 samples.

How the data were processed

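Total RNA from roots of Arabidopsis thaliana was measured on Affymetrix arrays, with 18 arrays from 6 genotypes and 3 arrays per genotype. Per the labels' protocols, plants grew in vitro on 10 mM NH4NO3 for 8 days, RNA was extracted with TRIzol, and biotin-labelled RNA was prepared with an Affymetrix 3' IVT Express kit. Group and replicate number were both taken from each sample's title.

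The authors deposited 1 table of intensity values for all arrays, on a linear scale with 22810 probe sets. The software that summarised the probes into probe sets and the background correction are not given in the sources used here. The values themselves show that every array was scaled to a mean of 500 after 2% of the probe sets was trimmed at each end, so differences between genotypes are relative to that common mean. Such scaling hides any change in the total amount of messenger RNA per root. Between 16.5% and 19.5% of the probe sets of an array lay under an intensity of 16, where background makes up much of the value.

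The 64 control probe sets were left out, and 22746 probe sets were tested. Values were transformed as log2(value + 16), and a fold on this scale understates the change of dim probe sets. A linear model with 1 coefficient per genotype was fitted over all 18 arrays with limma 3.58.1 in R 4.3.3, so that every comparison shared the spread of all genotypes, and the variances were moderated by empirical Bayes. Each of 10 comparisons was adjusted by the Benjamini-Hochberg method on its own, and a probe set was called at an adjusted p under 0.05. Every adjusted p of a gene comes from limma. A moderated F test over the 5 contrasts against the wild type was run as an omnibus test. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

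Depth has no equivalent on these arrays, and their number limits the precision. The median SD of a probe set between arrays of a genotype was 0.20 on the log2 scale. In data simulated for chl1-5 against col over 22746 probe sets, 67, 67 and 66 probe sets were changed by 0.5, 1 and 2 on the log2 scale. Of these, 20.9%, 68.7% and 93.9% were called, and 5 unchanged probe sets were called. The simulated arrays varied independently of each other, and the real comparison called 495 probe sets, so these shares need not hold for it. The labels do not say that the replicates of a genotype were separate cultures, so p-values measure only the spread between these samples, which can be technical.

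Probe sets were named from the platform annotation supplied with the series. It listed 1 gene for 13513 of the tested probe sets, several genes for 503 and none for 8730. Of the probe sets with 1 gene, 13436 were matched by gene ID to a RefSeq gene table of assembly TAIR10.1, which gave current symbols and was used for names, order and chromosome of genes only. Genes without a symbol are given by locus code. A probe set with several genes or none is not named, and where it is described it is called unnamed. The annotation used here named no probe set for NRT1.1, NRT2.1, NRT3.1, NIA1, NIR1 or AMT1.1, so these genes are not analysed here.

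Before the data were examined, the comparisons, the tests, the alternatives, 27 gene lists and the rule for naming genes were fixed. The rule took, for each comparison against the wild type and for T101A against T101D, the 8 genes with the largest rise and the 8 with the largest fall among called probe sets of 1 gene whose 3 arrays lay all above or all below the 3 of the other group. It added the called members of the fixed lists. For comparisons against chl1-5 it took 4 rises and 4 falls, and where under 3 probe sets passed, the 3 with the smallest unadjusted p. The 27 lists covered nitrogen transport, assimilation and signalling, other nutrients, hormones, defence, stress and cell type markers. They held 324 genes, of which 35 were measured here. None of these lists reached the 5 measured members needed for a set test, 11 had 0 measured members, and 3 genes were left out because the reference gave their symbol to another locus. A further 25 lists were written after the annotation was seen and before any comparison was made, from genes with a named probe set. Called members of these lists are also named below, outside the rule. Their single-gene calls were not run under the alternatives, unless the rule also named the gene in that comparison.

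The 25 lists were tested in 6 comparisons as 1 family of 150 tests, with limma's camera at a preset correlation between genes of 0.01, with camera at an estimated correlation, and with fry. The preset correlation gave 12 calls and the estimated correlation gave 0, with 17 at an unadjusted p under 0.05. fry, which tests whether a list's genes moved on balance 1 way and compares them with no other genes, gave 8 calls. Each list stood for a gene by its brightest probe set.

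The alternatives were 2 filters on dim probe sets, quantile normalization, centring each array on its median, a pseudocount of 1, an intensity trend with a robust prior, a fit of the compared arrays alone, the replicate number as a block, array weights, the mean of all probe sets of a gene, an estimated correlation in the list tests, and each array left out in turn. A fit without chl1-9 replicate 3 for the comparisons that do not hold chl1-9 was added after seeing the data. No pair of arrays differed so little that it was counted as 1 sample.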

Results

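Root transcripts of the wild type (col, the Columbia accession) were compared with those of 5 lines carrying changes in NRT1.1, the nitrate transporter and nitrate sensor of the root that is also known as CHL1 and NPF6.3. The lines were chl1-5, a known deletion mutant, chl1-9, a known point mutant, chl1-12, an allele whose lesion the labels do not describe, and T101A and T101D, in which the threonine T101 of the protein is replaced by a residue that cannot be phosphorylated or by one that mimics phosphorylation. The background that carries the T101 forms is not stated in the labels. Each genotype had 3 arrays, and levels are given as mean intensity ± SD with n = 3. Median intensities of the 18 arrays lay between 185 and 197. Correlations between arrays of 1 genotype, across probe sets, ranged from 0.978 to 0.989 and those between genotypes from 0.975 to 0.989. The ratio of the 5' to the 3' GAPDH control probe set was lowest in chl1-9 replicate 3, at 0.705, against up to 1.13 elsewhere.

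NRT1.1 itself was not analysed here, because no probe set was named for it. The 20 measured genes beside it in locus order, from AT1G11950 to AT1G12270, were followed in the 5 lines to see how far the chl1-5 deletion reached. Of 100 tests, 4 passed, all for the flavin-dependent monooxygenase gene FMO (AT1G12200). FMO rose in chl1-5 by 0.75 ± 0.12 (log2 ± SE), in chl1-9 by 0.60, in chl1-12 by 0.73 and in T101A by 0.59, with limma adjusted p between 0.00297 and 0.0141. In T101D the difference was 0.31, with an adjusted p of 0.337. Differences of all 20 neighbours lay between -1.02 and 0.82, and none fell past the threshold in chl1-5. Only genes with a named probe set could be followed, and 8730 tested probe sets had no listed gene. Genes beside NRT1.1 may therefore be missing, and how far the deletion reached stays open.

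**Figure D1:**
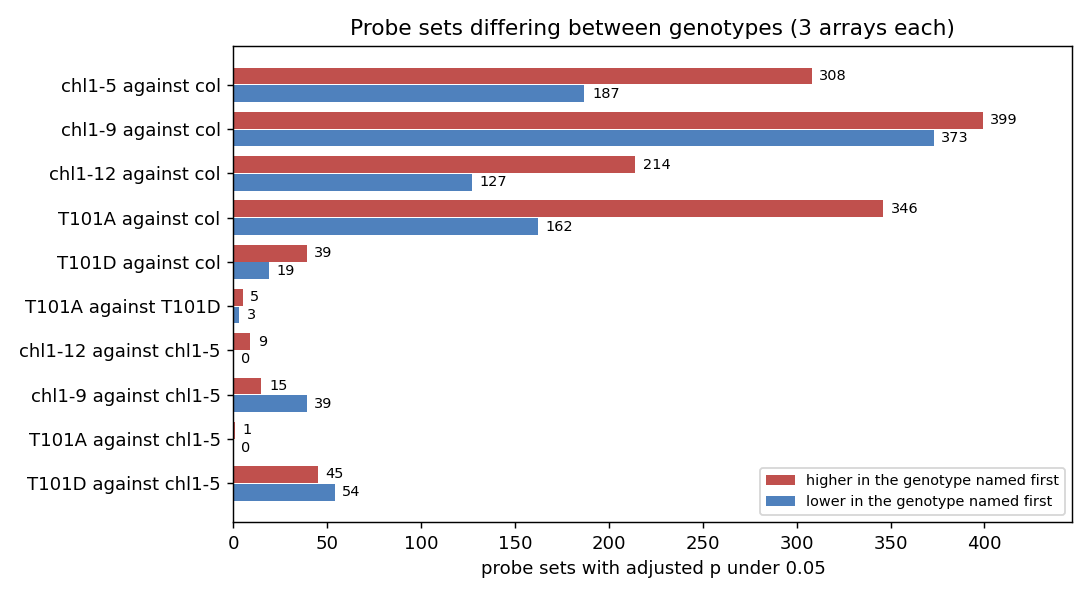
Number of probe sets with an adjusted p under 0.05 in each of 10 comparisons of 3 arrays with 3, drawn as horizontal bars that start at 0, red for higher and blue for lower in the genotype named first. Counts against col run from 58 in T101D to 772 in chl1-9, and the comparison of T101A with chl1-5 has 1.

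Loss of NRT1.1 in chl1-5 was accompanied by a strong rise of a pair of neighbouring genes for lipid-transfer-like proteins. AT4G12500 rose 10.4-fold, from 93.2 ± 18.3 in col to 1115 ± 105 in chl1-5, and AT4G12490 rose 3.83-fold to 636 ± 118. AT4G32950, a type 2C protein phosphatase gene, rose 9.12-fold, from 33.8 ± 4.9 to 447 ± 118. AT4G33720, which encodes a secreted protein related to PR-1, rose 8.25-fold, and the organic cation and carnitine transporter gene OCT1 rose 4.10-fold to 1266 ± 247. The peroxidase gene AT5G47000, AT4G37220 and the cell wall enzyme gene XTH26 rose between 3.11-fold and 4.08-fold. Limma adjusted p for these 8 genes lay between 6.3e-07 and 0.0119.

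Of the named genes that fell in chl1-5, 3 encode berberine-bridge-like oxidoreductases. AT1G26390 dropped from 1943 ± 444 in col to 138 ± 82 in chl1-5, AT1G26380 from 594 ± 44 to 75.6 ± 30.6, and AT1G26410 from 182 ± 10 to 20.6 ± 13.6. QQS, a gene known to affect the allocation of carbon and nitrogen between starch and protein, fell 11.4-fold, from 818 ± 73 to 57.7 ± 10.8 (limma adjusted p = 6.4e-06). The germin-like gene AT5G38910 fell 9.16-fold, AT3G60420 6.29-fold, the TIR-domain gene AT1G57630 4.36-fold, and ATKDSA2, which encodes an enzyme making a sugar acid of the cell wall, 5.88-fold. The largest fall of all probe sets in this comparison belonged to one for which no gene was listed, from 6595 ± 507 to 11.5 ± 15.2. Another unnamed probe set dropped from 4703 ± 246 to 56.2 ± 28.9, and it was also low in T101A (16.4 ± 6.5) and T101D (24.5 ± 18).

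Among genes known to be induced by nitrate, 1 of 17 rose in chl1-5 (AT4G32950) and 4 fell. The falling members were the repressor genes AT3G25790 (HHO1, -0.76 ± 0.15 log2, SE) and AT1G25550 (HHO3, -0.47), AT1G49500 (-1.24) and the membrane protein gene AT5G62720 (-0.43). The list as a whole did not stand apart (median -0.12, adjusted p = 0.75 with camera). Of 11 NPF transporters, the family of NRT1.1, AT1G59740 fell by 0.79 and AT2G26690 (NRT1.4) by 0.74 on the log2 scale. CC-type glutaredoxins, some of which act as shoot-to-root signals of nitrogen demand, had 3 of 17 members higher and 0 lower. AT1G06830 (CEPD1) rose 3.02-fold, AT3G62960 by 1.41 and AT4G33040 by 0.90 on the log2 scale. The list median was 0.47, with camera adjusted p = 0.000393 and adjusted p = 0.097 with an estimated correlation, and the median was 0.19 without col replicate 1. Root hair markers had 4 of 9 members higher, namely the peroxidase genes AT3G49960 (1.09) and AT4G26010 (0.69), the pectin methylesterase gene AT5G04960 (0.97) and the extensin gene AT3G54580 (0.70). Their median was 0.64, with camera adjusted p = 3.6e-09 and adjusted p = 0.203 with an estimated correlation. A different share of cell types was not tested and is not excluded, here or in the other lines. GSTU20 and GSTU28 rose among 11 glutathione transferases, whose camera adjusted p was 0.0354 and whose adjusted p was 0.286 with an estimated correlation. That list call was also lost above the median level (0.108), above the lowest quartile (0.0604), with the replicate number as a block (0.0587) and without col replicate 1 (0.0966), chl1-5 replicate 2 (0.127) or col replicate 3 (0.0752). BCAT4, which begins the chain elongation of methionine for glucosinolates, rose 1.92-fold.

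In all, 308 probe sets were higher and 187 lower in chl1-5 (495 of 22746), of which 69 and 80 differed by at least 2-fold, and 3071 had an unadjusted p under 0.05. Of the 35 measured genes of the lists fixed beforehand, 2 rose and 3 fell, and 4 rose and 3 fell when adjusted over the list alone. The count was 135 (64 higher, 71 lower) in a fit of the 6 arrays compared, 538 (387 higher, 151 lower) with arrays centred on their medians, 867 with array weights and 216 to 332 with 1 of the 6 arrays left out. AT4G12500, AT4G32950, QQS, AT1G26390 and ATKDSA2 passed the threshold in every alternative run for them, while AT3G60420 lost it in 5 of 13, AT1G25550 in 6 of 15 and AT3G25790 in 3 of 15.

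**Figure D2:**
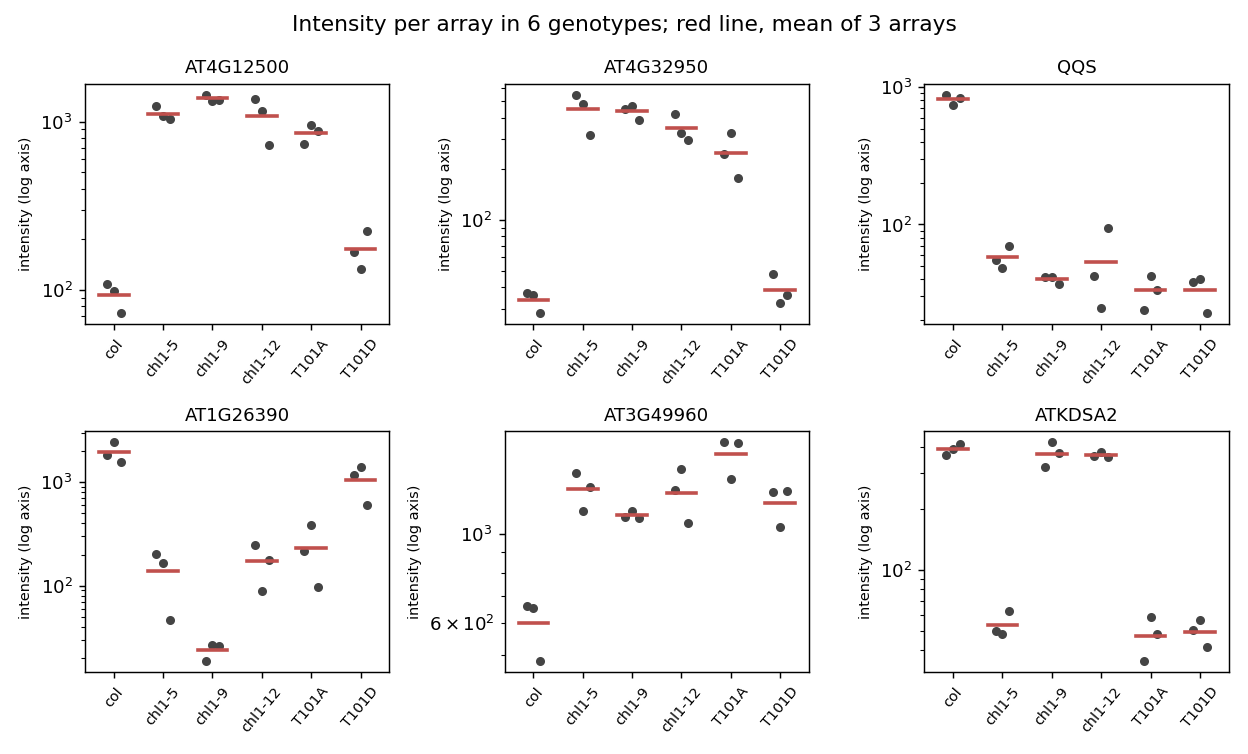
Intensity of 6 genes on every array (dots, logarithmic y axis with its own range for each gene) in 6 genotypes, with a red line at the mean of 3 arrays. AT4G12500 lies between 731 and 1450 in chl1-5, chl1-9, chl1-12 and T101A and below 224 in col and T101D, while QQS lies between 739 and 883 in col and below 95 in the 5 other lines.

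The point mutant chl1-9 was compared with col in the same way. AT4G12500 rose 12.9-fold to 1374 ± 66, AT4G32950 rose 9.08-fold to 436 ± 42, and OCT1 4.55-fold to 1389 ± 71. AT5G24240, which encodes a member of the phosphatidylinositol 4-kinase family, rose 17.7-fold, from 16.9 ± 6.3 in col to 563 ± 83. It did not pass against col in the other lines, at 32 ± 17 in chl1-5, 22 ± 1 in chl1-12, 22 ± 17 in T101A and 45 ± 17 in T101D. The glycosyltransferase gene AT3G55700, AT4G33720, AT5G47000 and AT1G06830 rose by 1.71 to 2.202 on the log2 scale, and the call of AT4G33720 was lost in 6 of 15 alternatives. The extensin-like gene AT3G28550 fell from 735 ± 142 to 6.47 ± 7.08 (limma adjusted p = 3.8e-10). It too did not pass in the other lines, at 767 ± 26 in chl1-5, 785 ± 67 in chl1-12, 766 ± 66 in T101A and 654 ± 81 in T101D. AT1G26390 fell from 1943 ± 444 to 23.9 ± 4.5, AT1G26380 to 22.7 ± 7.4, AT1G26410 to 4.39 ± 3.37, and AT5G38910 20.3-fold to 84.5 ± 17.5. QQS fell 14.9-fold, AT3G60420 9.70-fold, and AT2G15220, which encodes a secreted protein, 8.30-fold.

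AT2G26690 (NRT1.4) fell by 1.13 ± 0.15 (log2, SE) and AT1G59740 by 0.72 in chl1-9, the 2 of 11 NPF genes that passed. Among the 17 nitrate-induced genes 3 rose, AT4G32950, AT2G48080 (0.87) and AT5G41670 (PGD3, 6-phosphogluconate dehydrogenase, 0.72), while AT1G49500 (-0.98) and AT3G25790 (HHO1, -0.57) fell. The fall of AT3G25790 had an adjusted p of 0.0492 and was lost in 11 of 15 alternatives. CC-type glutaredoxins had 3 of 17 members higher, AT1G06830 (1.71), GRX480 (0.77) and AT4G33040 (0.63), with a median of 0.63, camera adjusted p = 0.00185 and adjusted p = 0.101 with an estimated correlation. Root hair markers had AT3G49960 (0.89) and AT5G04960 (0.72) higher, a median of 0.33, camera adjusted p = 0.00566 and adjusted p = 0.593 with an estimated correlation. Without chl1-9 replicate 2 the median was 0.18 (adjusted p = 0.0799), and without col replicate 3 the adjusted p was 0.0947. RCA, a marker of green shoot tissue, was at -0.34 in chl1-9 with a limma adjusted p of 0.553, and a different share of tissues was not excluded. Sugar transporter SWEET2 fell by 1.62 on the log2 scale and SWEET14 and SWEET8 rose by 0.54 and 0.93. Cytochromes P450 had 3 of 23 members lower, CYP71B23 (-1.42), CYP71B6 (-0.94) and CYP71B28 (-0.64). UGT72E1 (1.05), UGT72B3 (0.92) and the flavonol rhamnosyltransferase gene UGT78D1 (0.58) rose and UGT76E2 (-0.48) fell among 51 glycosyltransferases, a list with camera adjusted p = 0.0567. BCAT4 rose 2.26-fold. The 69 genes of the plastid genome had a median of -0.58, with camera adjusted p = 4.0e-05, adjusted p = 0.775 with an estimated correlation and 0 members called. Their median was 0.05 without chl1-9 replicate 3, the array with the low GAPDH ratio.

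In chl1-9, 399 probe sets were higher and 373 lower than in col (772), 98 and 139 of them by at least 2-fold, and 3535 had an unadjusted p under 0.05. Without chl1-9 replicate 3, 581 were called. Of the 35 genes fixed beforehand, 3 rose and 2 fell, and 4 rose and 3 fell when adjusted over the list alone. The count was 160 (69 higher, 91 lower) in a fit of the 6 arrays compared and fell to 453 without col replicate 2. With arrays centred on their medians, 521 of 839 called probe sets were higher, against 399 of 772.

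SP1L5, a gene of the SPIRAL1-like family of microtubule-associated proteins, rose 30.2-fold in the allele chl1-12, from 196 ± 62 in col to 6221 ± 479. It did not pass against col in the other lines, at 116 ± 11 in chl1-5, 122 ± 80 in chl1-9, 112 ± 48 in T101A and 170 ± 51 in T101D. AT4G12500 rose 9.85-fold to 1084 ± 323, AT4G32950 7.22-fold to 346 ± 63, and AT4G33720, AT4G12490 and AT5G47000 between 3.97-fold and 5.22-fold. AT1G43590 rose from 2.33 ± 1.06 to 89.2 ± 20.8 and AT1G44510 from 15.1 ± 14.5 to 105 ± 3. QQS fell 13.04-fold to 53.6 ± 36.2, AT1G26390 10.97-fold to 172 ± 81, AT5G38910 7.15-fold and AT1G26380 6.91-fold. AT3G60420, AT1G57630, the jacalin lectin gene AT5G35940 and AT4G39675 fell between 3.65-fold and 6.55-fold. The unnamed probe set with the largest fall in chl1-5 was at 347 ± 46 in chl1-12 (-4.19 ± 0.24 log2, SE).

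Nitrate-induced genes in chl1-12 had 4 of 17 members lower, AT1G49500 (-1.45), AT3G25790 (HHO1, -0.77), AT5G62720 (-0.60) and AT1G25550 (HHO3, -0.59), and AT4G32950 higher. The list's camera adjusted p was 0.521. AT1G59740 was the only one of 11 NPF genes past the threshold, at -0.76. CC-type glutaredoxins had 3 of 17 members higher, AT1G06830 (1.31), AT5G11930 (1.08) and AT4G33040 (0.99), with a median of 0.33, camera adjusted p = 0.00815 and adjusted p = 0.155 with an estimated correlation. Without col replicate 1 that median was 0.03 (adjusted p = 0.0584). Root hair markers AT3G49960 (1.06) and AT5G04960 (0.76) rose, with a list median of 0.56, camera adjusted p = 1.7e-09 and adjusted p = 0.203 with an estimated correlation. The hydroxycinnamate glucosyltransferase gene UGT84A1 fell by 1.19 on the log2 scale. BCAT4 rose 1.802-fold.

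Against col, 214 probe sets were higher and 127 lower in chl1-12 (341), 61 and 67 by at least 2-fold, and 2515 had an unadjusted p under 0.05. Of the 35 genes fixed beforehand, 2 rose and 2 fell, and 5 rose and 4 fell when adjusted over the list alone. The count was 95 (43 higher, 52 lower) in a fit of the 6 arrays compared, 536 with array weights and 181 to 292 with 1 of them left out. The call of AT1G06830 was lost in 8 of 15 alternatives, those of AT3G60420 and AT1G57630 in 6 of 13 and that of AT4G33720 in 5 of 15.

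T101A, the form that cannot be phosphorylated at this threonine, was compared with col. AT4G12500 rose 8.02-fold to 856 ± 111, AT4G32950 5.19-fold to 248 ± 75, AT4G33720 5.83-fold and AT5G47000 4.42-fold to 538 ± 74. XTH26, AT4G37220, AT5G04120 and OCT1 rose between 3.22-fold and 3.45-fold. QQS fell 17.1-fold to 33.2 ± 9.2, AT1G26390 8.80-fold to 232 ± 144, ATKDSA2 6.51-fold to 47.3 ± 11.4 and AT5G38910 5.72-fold. AT3G60420, AT1G26380, AT5G35940 and AT4G39675 fell between 4.02-fold and 4.79-fold, and the call of AT3G60420 was lost in 6 of 13 alternatives. Limma adjusted p for these 16 genes lay between 8.5e-08 and 0.0388.

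Root hair markers had 5 of 9 members higher in T101A, AT3G49960 (1.38 ± 0.15 log2, SE), AT5G04960 (1.06), AT4G26010 (0.71), AT3G54580 (0.66) and the expansin gene EXPA18 (0.56). RCA, a marker of green shoot tissue, was at -0.56 in this line with an adjusted p of 0.261, and a different share of tissues was not excluded. The root hair markers had a median of 0.67, with camera adjusted p = 2.0e-10 and adjusted p = 0.189 with an estimated correlation. The CC-type glutaredoxin AT4G33040 rose by 0.90, while AT1G06830 (1.21, adjusted p = 0.0505) and BCAT4 (0.66, adjusted p = 0.0584) did not pass. Of the 17 nitrate-induced genes AT4G32950 passed, and AT3G25790 (HHO1) was at -0.33 with an adjusted p of 0.28. Calmodulin-like genes had a median of 0.27 with 0 of 8 members called and 7 of 48 tests over 6 comparisons at an unadjusted p under 0.05. Their camera adjusted p was 0.0482, and adjusted p = 0.274 with an estimated correlation, and the call was also lost in 7 other alternatives. AT1G59740 fell by 0.76, SWEET14 rose by 1.13, and the plastid gene rps3 fell by 0.42 on the log2 scale.

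In T101A 346 probe sets were higher and 162 lower than in col (508), 72 and 57 by at least 2-fold, and 3648 had an unadjusted p under 0.05. Of the 35 genes fixed beforehand 1 rose, EXPA18, and 8 rose and 2 fell when adjusted over the list alone. The count was 45 in a fit of the 6 arrays compared, 226 to 540 with 1 of them left out, 879 with the replicate number as a block, 832 with an intensity trend, 819 with array weights and 789 above the median level. With arrays centred on their medians, 469 of 595 called probe sets were higher, against 346 of 508.

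T101D, the form that mimics phosphorylation, had the fewest probe sets differing from col. QQS fell 17.0-fold to 33.6 ± 9.6, ATKDSA2 6.25-fold to 49.5 ± 7.8, AT3G61610 3.49-fold from 222 ± 23 to 52.1 ± 3.9, and AT5G35940 3.42-fold to 201 ± 51. The sugar transporter gene SWEET14 rose 2.295-fold, from 126 ± 1 to 311 ± 40, and AT1G43590 rose from 2.33 ± 1.06 to 42.0 ± 9.4. AT2G04210, the cytochrome P450 gene AT5G08250, AT1G51840, the root hair peroxidase gene AT3G49960, the citrate exporter gene AT1G51340 and AT4G33730 rose between 1.91-fold and 4.40-fold. The rhodanese-like gene AT2G42220 fell to 4.48 ± 4.11. HPR, the hydroxypyruvate reductase of photorespiration, fell by 1.35 ± 0.25 (log2, SE), SBPASE, a Calvin cycle phosphatase gene, by 1.295, and the photosystem gene AT1G51400 by 1.13, with limma adjusted p of 0.0428, 0.0428 and 0.0484. RCA, the measured marker of green shoot tissue, stood at -1.11 ± 0.24 with an adjusted p of 0.0744.

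Several genes called in the 4 other lines did not pass in T101D. AT4G12500 was at 175 ± 46 (adjusted p = 0.154), AT4G32950 at 38.8 ± 8.1, AT1G26390 at 1052 ± 409 (adjusted p = 0.542) and AT5G38910 at 1497 ± 484 (adjusted p = 0.788). Nitrate-induced genes had 0 of 17 members past limma's threshold and a median of 0.13, with camera adjusted p = 0.0236 and adjusted p = 0.258 with an estimated correlation, and the call was also lost above the median level (0.0855) and without T101D replicate 1 (0.181), T101D replicate 3 (0.0713) or col replicate 3 (0.0785). Root hair markers had a median of 0.56 with AT3G49960 (0.98) called, camera adjusted p = 2.5e-10 and adjusted p = 0.189 with an estimated correlation, and with RCA at -1.11 a different share of tissues was not excluded. The peptide gene RALFL27 rose by 0.70 on the log2 scale.

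In T101D 39 probe sets were higher and 19 lower than in col (58), 9 and 13 by at least 2-fold, and 2420 had an unadjusted p under 0.05. Of the 35 genes fixed beforehand 0 passed in limma, 11 had an unadjusted p under 0.05, and 6 rose and 2 fell when adjusted over the list alone. The count was 4 (0 higher) in a fit of the 6 arrays compared, 12 without col replicate 3, 14 without T101D replicate 1, 158 with an intensity trend and 154 above the median level, and with arrays centred on their medians 85 were higher and 20 lower. The falls of HPR, SBPASE and AT1G51400 were each lost in 8 or 9 of the alternatives, and the calls of AT2G42220 and AT1G51840 in 7 of 14.

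The comparison of T101A with T101D asked what the residue at this position changed, and 8 probe sets differed. AT4G32950 was 4.73-fold higher in T101A (248 ± 75 against 38.8 ± 8.1) and AT4G12500 4.64-fold higher (856 ± 111 against 175 ± 46), both with limma adjusted p = 3.0e-04. AT2G04210 was lower in T101A, at 5.57 ± 6.79 against 82.4 ± 24.7 (adjusted p = 0.0236, lost in 6 of 13 alternatives), and AT1G43590 was at 3.58 ± 1.23 against 42.0 ± 9.4 (adjusted p = 3.0e-04). QQS was at 33.2 ± 9.2 and 33.6 ± 9.6 (adjusted p = 0.999), and AT1G26390 was at 232 ± 144 and 1052 ± 409 (adjusted p = 0.249). The root hair markers differed by a median of 0.09 (camera adjusted p = 0.157).

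The 308 probe sets higher in chl1-5 had a median of 0.25 in T101A against T101D, with 283 above 0, and the 187 lower ones a median of -0.29, with 27 above 0. Camera with an estimated correlation gave p = 6.8e-05 and p = 1.7e-05 for these sets in this contrast of 3 arrays with 3, which holds no col and no chl1-5 array. In all, 5 probe sets were higher and 3 lower in T101A than in T101D, and 1486 had an unadjusted p under 0.05. Of the 35 genes fixed beforehand 0 passed and 5 had an unadjusted p under 0.05. When adjusted over the list alone, 0 were higher and 2 lower in T101A. A fit of these 6 arrays alone called 0, and 16 were called above the median level and 20 with an intensity trend.

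**Figure D3:**
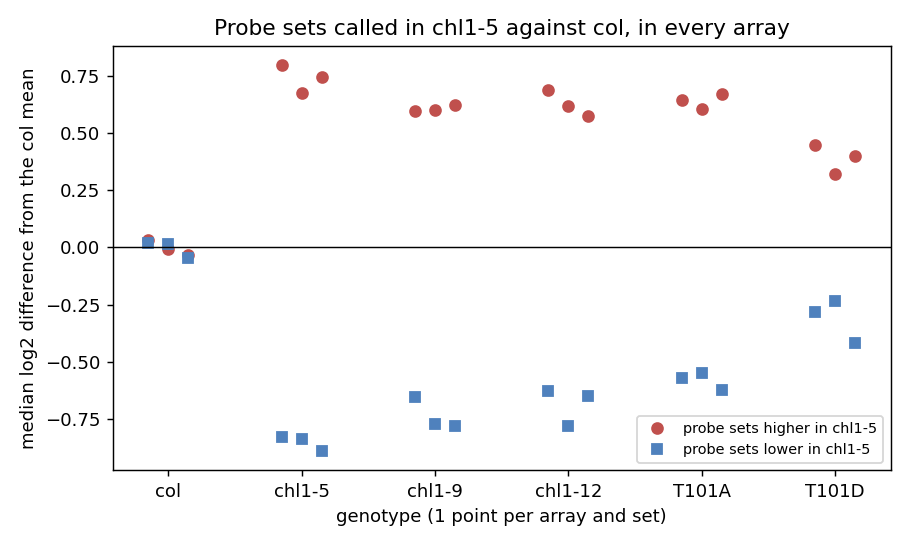
Median log2 difference from the col mean, on each of the 18 arrays, of the 308 probe sets higher in chl1-5 (red circles) and the 187 lower (blue squares), by genotype, with a black line at 0. The sets were chosen by comparing chl1-5 with these col arrays, which inflates every distance from col, while the distance between T101A and T101D is free of that choice.

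The lines were also compared with chl1-5, which gives the difference between their effects because the wild type drops out. In T101A 1 probe set differed, the unnamed one with the largest fall in chl1-5, at 5394 ± 250 against 11.5 ± 15.2 (limma adjusted p = 1.4e-10), and 1913 had an unadjusted p under 0.05. The annotation used here lists no gene for it, so whether it measures NRT1.1 itself stays open. The next genes, AT1G26800 (-1.25) and AT1G43590 (-1.004), did not pass, with an adjusted p of 0.0618. That probe set stood at 6595 ± 507 in col, 10860 ± 879 in chl1-9 and 11740 ± 204 in T101D. In chl1-12, 9 probe sets were higher than in chl1-5 and 0 lower, with 938 at an unadjusted p under 0.05 in limma. SP1L5 was 47.3-fold higher, ATKDSA2 5.52-fold, AT3G61610 3.11-fold and AT1G43590 2.65-fold. The chl1-9 line had 15 probe sets higher and 39 lower than chl1-5, but 21 and 19 without chl1-9 replicate 1 and 6 and 4 in a fit of the arrays compared. AT5G24240 was 12.7-fold higher, ATKDSA2 5.59-fold, AT3G61610 2.95-fold and the metal transporter gene AT3G58060 2.93-fold, while AT3G28550 was 35.9-fold lower and AT2G15220, AT2G19970 and CYP71B23 were between 2.17-fold and 2.35-fold lower. T101D had 45 probe sets higher and 54 lower than chl1-5, but 43 and 39 after quantile normalization and 46 and 37 with arrays centred on their medians. AT1G26390 was 7.45-fold higher in T101D, AT5G38910 6.59-fold, AT1G26380 4.93-fold and AT2G04210 3.83-fold, and AT4G32950 was 8.31-fold lower, AT4G12500 6.03-fold, AT4G33720 5.57-fold and AT2G42220 3.45-fold. The call of AT4G33720 was lost in 9 of 15 alternatives and that of AT2G42220 in 7 of 14, as was that of AT2G15220 between chl1-9 and chl1-5 in 9 of 15. Calls of the T101D rises were lost as well, AT1G26380 in 6 of 14, AT2G04210 in 6 of 13, and AT1G26390 and AT5G38910 each in 5 of 15. AT4G32950 and AT4G12500 kept theirs in every alternative. A fit of the arrays compared gave 10 for chl1-9 and 7 for T101D, against 54 and 99, and without chl1-5 replicate 3 the counts were 19 and 23.

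Changes were shared between lines. In all 5 lines 27 probe sets differed from col in the same direction, 23 higher and 4 lower, and 178 did so in chl1-5, chl1-9, chl1-12 and T101A. Those shared by all 5 included QQS, AT5G35940 and AT2G15260 among the lower ones and AT3G49960, SWEET14, RALFL27, AT1G51340 and BAT1 among the higher ones. Between chl1-5 and T101A, 195 higher and 75 lower calls were shared, and between chl1-5 and chl1-9 the shared calls were 193 and 115. T101D shared 33 higher and 7 lower calls with chl1-5. Simulations of unchanged groups against the same col arrays shared at most 1 call in any pair, but they hold no changed genes. No probe set was called in opposite directions in any of the 10 pairs. All 5 comparisons use the same col arrays, which by itself favours calls in the same direction. Correlations of log2 differences across probe sets, which are not independent replicates, ranged from 0.46 to 0.73 over the 10 pairs, where 100 simulations of unchanged groups against the same col arrays gave means of 0.50. Covariances exceeded the simulated 0.022 by 0.021 to 0.045. The 3 col arrays cannot be split into separate control groups of at least 2. How much of the excess and of the shared calls comes from the shared controls therefore stays open. Across the 6 genotypes, 598 probe sets (2.63%) passed the omnibus F test.

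In the low oxygen list of 16 genes AT5G66985 rose in chl1-5, chl1-9, chl1-12 and T101A by 1.91-fold to 2.17-fold, while AT4G39675 fell in chl1-9, chl1-12 and T101A. Xyloglucan enzymes XTH20 (0.65 to 0.75) rose in the same 4 lines, XTH26 in 3 of them, and XTH33 fell by 0.94 in chl1-9. Just short of a call were AT4G39675 in chl1-5, at -1.48 (limma adjusted p = 0.0501), and XTH26 in chl1-12, at 1.26 (limma adjusted p = 0.0509). UGT72E1, which glycosylates lignin precursors, rose by 0.88 to 1.05 in chl1-5, chl1-9, chl1-12 and T101A. RALFL27 rose in all 5 lines by 0.698 to 1.104, as did SWEET14 by 0.540 to 1.199. In the iron deficiency list of 12 genes AT3G58060 fell by 1.24 in chl1-5 and AT3G07720 rose by 0.59 in chl1-9. Over 6 comparisons the XTH genes had 8 calls in 60 tests, the RALFL peptides 5 in 60, the low oxygen list 7 in 96 and the SWEET genes 7 in 96. The beta-glucosidases had 3 calls in 132 tests, the carboxypeptidase-like genes 2 in 174, the TBL genes 2 in 138, the ubiquitin-conjugating enzymes 2 in 78, the expansins 1 in 60 and the tetraspanins 1 in 90. Limma gave 0 calls in 48 tests of aldehyde dehydrogenases, 90 of IQD calmodulin-binding genes, 132 of BZIP factors and 42 of WRKY factors, with 10, 14, 5 and 2 at an unadjusted p under 0.05.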

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

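The tests of scaling and of single arrays were written before their values were seen. That of common descent was written before its counts were seen, but it concerns a pattern named by genes found in these data. Those of the plastid genome, of a chromosome stretch and of mislabelled arrays were chosen after the pattern was seen.

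On the probe sets called in chl1-5, T101A lay further in the direction of chl1-5 than T101D did. Array scaling would shift the higher and the lower probe sets of chl1-5 the same way, but between T101A and T101D they moved apart, by 0.537 between their medians. A single array was argued against by the lowest such value in 9 pairings of a T101A with a T101D array, 0.283. What stays open is a difference between the lines other than the residue at T101, because each form came from 1 line. The unnamed probe set with the largest fall in chl1-5 was at 5394 ± 250 in T101A and 11740 ± 204 in T101D. That gap, -1.12 ± 0.24 (log2 ± SE), was far larger than the SD of either line. Its limma adjusted p of 0.187 uses a spread shared by all genotypes, among them chl1-5 at 11.5 ± 15.2. This p therefore cannot tell whether the level was the same in T101A and T101D. Whether the probe set measures NRT1.1, and so the level of each form, stays open. The lines differed at 8 probe sets, which cannot separate the residue from the line.

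Genes of the plastid genome were lower in chl1-9, with a median of -0.58. Loss of plastid transcripts in all chl1-9 roots was argued against, because 2 of 3 arrays lay at or above the lowest col array. The median was 0.0543 without chl1-9 replicate 3, which also had the lowest ratio of the GAPDH control, so 1 array may carry the whole shift. Replicate 3 was the lowest array in each of the 6 genotypes, at -1.6 in chl1-9 and between -0.0973 and -0.328 in the others, and what made these arrays differ stays open.

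ATKDSA2, AT3G61610 and an unnamed probe set were low in chl1-5, T101A and T101D and not in chl1-9 or chl1-12. A stretch of 1 chromosome that holds all of them was argued against, because 1 of the genes, AT3G61610, lies on another chromosome than ATKDSA2. The unnamed probe set has no listed chromosome, so a stretch that holds it and 1 of the genes stays open. Arrays of 1 genotype mislabelled as all 3 lines were argued against by the 99 probe sets that differed between T101D and chl1-5. That count does not cover the other pairs, which differed at 1 probe set (T101A and chl1-5) and at 8 (T101A and T101D). Descent of these lines from a common parent could give the pattern, with 3 such probe sets against at most 2 in the other choices of 3 lines from 5, but the 3 counted are the pattern's own, so it stays open.

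Regrouping the arrays of a comparison at random gives 10 splits, which cannot give a share under 0.05. The real split was matched by 1 of 10, itself, in every comparison but T101A with chl1-5, where it was 2 of 10. Counts of the real split and the highest other were 495 and 1 for chl1-5, 772 and 2 for chl1-9, 341 and 1 for chl1-12, 508 and 1 for T101A and 58 and 2 for T101D, each against col. They were 8 and 3 for T101A against T101D, and against chl1-5 they were 9 and 1 for chl1-12, 54 and 1 for chl1-9, 1 and 1 for T101A and 99 and 2 for T101D. For the omnibus test 598 probe sets differed, against at most 89 in the regroupings, and 1 of 100 groupings, the real one, reached that count. Effects against col differed between lines at these same 8, 9, 54, 1 and 99 probe sets.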

How the results depend on the processing

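QQS, AT4G12500 and AT4G32950 kept their calls against col under every alternative run where they had passed. Of 1746 alternatives for 121 named values 1486 stayed the same, 249 were weaker (the call was lost), 11 stronger and 0 reversed. The losses were uneven. A fit of the compared groups alone lost the calls of 60 of the 121 values, and a pseudocount of 1 lost 19. With 1 array left out, 160 of 726 were lost. Where the cause is not given it was not tested. Above the median level the counts were 789 for T101A and 154 for T101D against col, 16 for T101A against T101D, 4 for chl1-12, 127 for chl1-9, 3 for T101A and 161 for T101D against chl1-5, and 901 in the omnibus test. Above the lowest quartile they were 115 for T101D, and 3 for T101A and 170 for T101D against chl1-5, and after quantile normalization 3 for T101A against chl1-5. With arrays centred on their medians T101D had 105. A pseudocount of 1 gave 37 for T101D, and 6 for T101A and 59 for T101D against chl1-5. An intensity trend with a robust prior gave 832 for T101A, 158 for T101D, 20 for T101A against T101D, 123, 2 and 200 for chl1-9, T101A and T101D against chl1-5, and 1024 in the omnibus test. A fit of the compared groups alone, with fewer arrays, gave 135, 160, 95, 45 and 4 for chl1-5, chl1-9, chl1-12, T101A and T101D, 0 for T101A against T101D, and 10 and 7 for chl1-9 and T101D against chl1-5. The replicate block gave 879 for T101A and 91 for T101D, and 4 and 158 for T101A and T101D against chl1-5. All 18 arrays were closest to arrays of their own number (median r 0.0627 against -0.0355 across probe sets), a hint of shared preparation. The main fit, which gave the counts and adjusted p of the results, does not model this. Array weights gave 867, 698, 536, 819 and 111 for chl1-5, chl1-9, chl1-12, T101A and T101D, and 7 and 210 for T101A and T101D against chl1-5. Gene lists had 12 calls and 0 with an estimated correlation. Without chl1-9 replicate 3 as a doubted array, an alternative chosen after seeing the data, T101A against chl1-5 had 4, and the median of the plastid genes in chl1-9 was 0.0543 (adjusted p = 0.753), while without chl1-9 replicate 2 it was -0.951.

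With 1 array left out, and so fewer arrays, chl1-5 had 216 to 332 (327 and 265 without col 1 and 2, 280, 317 and 216 without chl1-5 1, 2 and 3), chl1-9 453 to 685 (453 and 477 without col 2 and 3), chl1-12 181 to 292 (209 and 222 without col 2 and 3, 181 and 189 without chl1-12 1 and 2), T101A 226 to 540 (269 and 226 without col 2 and 3, 248 and 226 without T101A 1 and 3) and T101D 12 to 80 (12 without col 3, 14, 25 and 19 without T101D 1, 2 and 3). T101A against T101D had 4 to 13 (13 and 4 without T101A 2 and 3, 4 without T101D 3). Against chl1-5, chl1-12 had 7 to 9, chl1-9 19 to 53 (22, 26 and 19 without chl1-5 1, 2 and 3), T101A 1 to 3 (3, 3 and 2 without T101A 1, 2 and 3, 2 without chl1-5 2) and T101D 23 to 72 (41, 61 and 23 without chl1-5 1, 2 and 3, 24 and 35 without T101D 1 and 2). The omnibus test had 384 to 591 (384 and 387 without col 2 and 3), the neighbours of NRT1.1 3 to 5, the gene lists 9 to 14, and the mean correlation between lines lay from 0.593 to 0.679.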

Other observations

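The group of photosystem genes was chosen after the values were seen, so no group test is given.

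The values of 8 measured genes of the photosystems and their antennae are given without a call. These genes (PSBY, PSAN, LHCB4.1, PSAE-1, LHCB4.2, PSB27, LHCB4.3 and PSBW) had a median log2 difference from col of -1.09 in T101D, with all 8 below 0. The median was -0.64 in T101A, -0.57 in chl1-9, -0.14 in chl1-12 and -0.08 in chl1-5. In limma 0 of the 8 passed in any of 6 comparisons, and 7 had an unadjusted p under 0.05 in T101D. AT1G51400, a photosystem gene outside this group, fell by 1.13 in T101D with a limma adjusted p of 0.0484. RCA, the marker of green tissue, was at -1.11 in the same line with a limma adjusted p of 0.0744.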
